A study of Mus musculus with 31 samples.

How the data were processed

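RNA was measured in 15 fetal heads and 16 placentas, each on its own 1-colour (Cy3) Agilent 8x60K mouse expression array of design 074809. Per the labels, conceptuses were collected 12 days after plug detection from mothers of 10 to 23 weeks (young) or 42 to 65 weeks (old), and male conceptuses were chosen. The strains were C57 (also written B6 in the labels) and BTBR, an inbred mouse strain often used as a model of autism. The labels give 8 groups: in each tissue, 2 sets of young C57, 1 of young BTBR and 1 of old C57, with 4 arrays each except the heads of young C57 set 1, which had 3. No arrays of old BTBR mothers were analysed here.

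Per the file headers, the authors scanned the arrays with Feature Extraction 10.7.3.1, which subtracts background and removes spatial trends. The deposited processed signal of each scanner file is an intensity on a linear scale with no scaling between arrays, and the spot and local background medians used in 1 alternative are intensities as well. The deposited columns that mark spots as saturated, as not uniform, as out of line with their replicates or as well above background are yes-or-no marks, recorded here under the unit other, per the file headers. The deposited value table of the series is also an intensity on a linear scale. Its 31 columns shared the same distribution (median 125.133 in each) and ranked probes as the scanner files did (lowest Spearman correlation 1.0), so the authors had quantile normalized both tissues together. The processing notes name Partek without a version, and the authors' own tests were not used.

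Each array held 59305 non-control spots for 56605 probes. A probe was left out where it had no unmarked spot on some array, which removed 548 probes and kept 56057. Per array, 47 to 693 spots were marked as not uniform or out of line with their replicates and left out, and no spot was saturated (0 over all arrays). The 75th percentile of the processed signal ranged from 638.7 to 1115.7 per array, and 74.7% to 82.1% of probes lay well above background. The number of arrays limits the precision of each value.

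The signals of a probe's unmarked spots were averaged and put on the log2 scale, and each array's 75th percentile was subtracted. All log2 values below are on this scale, so 0 is the 75th percentile of an array. Probes were named by matching the transcript accession in the scanner files, without its version, to a RefSeq gene table of assembly GRCm38.p6. Of the probes kept, 34146 matched 1 symbol and 21911 matched none, and the symbols numbered 23593. The probe with the highest mean stood for its gene. The same table gave gene identifiers and named 958 of the 959 entries of the gene lists. The array's own positions refer to another assembly (mm9), so no coordinates are given. A gene was tested where its probe was well above background on every array of at least 1 group.

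Gene tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided moderated test) on all arrays of a tissue with 1 mean per group. Adjusted p is the Benjamini-Hochberg value over all genes tested, with a threshold of 0.05. The design, these tests, the gene lists and the rule for named genes were fixed before the data were examined. Each slide held 2 groups of 1 tissue, and 4 slides were used. Old C57 was compared with young C57 set 2 on their shared slide, and BTBR with young C57 set 1 on theirs. Within a slide each group filled its own row, so group and row cannot be told apart. Both young C57 sets were compared as a control across slides, where set and slide cannot be told apart. The series text states 4 litters per maternal age group. By the conceptus codes, whose reading is a choice made here, sets 1 and 2 shared litters, so they were not pooled. The code of old C57 replicate 4 begins like those of most young C57 conceptuses, and those of old replicates 1 and 2 begin alike. The labels do not say what the start of a code stands for. Whether conceptuses shared a parent, within or between age groups, is therefore not known, and the main tests treat them as independent.

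Head and placenta of the same conceptus were matched by its code. Whether an effect differed between tissues was tested with limma on the head minus placenta difference of 15 conceptuses. Head and placenta were compared directly in the 7 young C57 conceptuses with both tissues, with conceptus as a block. This pooled sets 1 and 2, which by the same reading come from 4 litters, so siblings counted as separate replicates. Tissues lay on separate slides, so tissue and slide cannot be told apart.

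Fixed gene lists for cell types, tissues, pathways and complexes numbered 46. Those with at least 3 measured members were tested, 36 in each head and 32 in each placenta comparison, with limma's camera at its preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with a correlation estimated from the residuals and limma's fry were alternatives. Fry asks whether a list's genes move, on balance, one way, without comparing them with other genes. Beside each list, the count of members past the threshold over all genes is given with the count adjusted over the list alone.

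Named genes followed a rule. For the age, strain and tissue comparisons, they are the 12 largest increases and 12 largest decreases among genes with adjusted p under 0.05 whose groups did not overlap in any array. Clone, accession, Rik, Gm and LOC names were left out. Where fewer than 5 genes passed in a direction, the 8 smallest p values in it are named as not passing. For the set comparisons and the tissue differences the number is 5 in each direction. From each list, up to 4 members with the smallest p past the threshold over the list alone could be named. Xist, Ddx3y, Kdm5d, Eif2s3y and Uty were read as checks of the sex label, and Nnt and Disc1 as checks of the strain label. Other genes named from a list were chosen after their values were seen. Where a gene was nowhere well above background in a group, that group was set to at least the lowest signal called above background on each array, and the fold is given as a bound ("at least").

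The pipeline was tested on simulated data. For the comparison of old with young heads, limma recovered 79.1%, 85.1% and 97.0% of simulated genes changed 1.5-, 2- and 4-fold, and for the placentas 43.3%, 67.2% and 92.4%. For strain, the shares were 65.7%, 83.6% and 98.5% in heads and 41.8%, 71.6% and 93.9% in placentas. For the differences between tissues they were lower, at 17.9%, 49.3% and 80.3% for age and 9.0%, 53.7% and 74.2% for strain. The simulation drew each gene on its own, so it leaves out variation that genes share on real arrays. These shares therefore do not tell what changes the real tests could miss.

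The alternatives were quantile normalization, median centring, normexp background correction (offset 50) with quantile normalization, the deposited value table, no filter, a stricter filter, all probes, eBayes with trend and robust options, only the compared groups, the replicate number as a block, pooled young sets with and without litter code as a block, a fold minimum of 1.5, and leaving out each array in turn. Normexp used the median spot and background signals, because the files hold no mean spot signal, so it changed the signal, the background correction and the scaling together. Likewise the pooled sets with litter code changed both the control and the block. Added after the data were seen were fits without 1 doubted head or placenta, and a test of the placenta lists in the heads. Other splits of the samples into groups of the same sizes (35, or 64 for the tissue comparison) were also fitted. Tables and plots used version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.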

Results

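The data are 31 array profiles of heads and placentas from mouse conceptuses collected 12 days after plug detection. The heads came from 4 conceptuses of old C57 mothers, 4 of young C57 set 2, 3 of young C57 set 1 and 4 of young BTBR mothers. The placentas numbered 4 in each of these groups. The 75th percentile of the signal lay between 752.4 and 1016.7 in the heads and between 638.7 and 1115.7 in the placentas. It differed without overlap between old heads (767.6 to 864.2) and set 2 (868.3 to 1016.7) and between BTBR heads (752.4 to 821.4) and set 1 (839.3 to 943.3). The same held for BTBR placentas (775.6 to 1115.7) and set 1 (638.7 to 699.7), while old and set 2 placentas overlapped. Whether this bears on the comparisons after scaling was not tested. Between 74.7% and 82.1% of probes were well above background, and the number of arrays limits the precision of each value. Values are log2 signals relative to each array's 75th percentile, given as mean ± SD. All heads had Y-linked RNA. The placenta labelled old C57 replicate 4 had none, with Ddx3y at -7.98, Kdm5d at -8.18 and Xist, the RNA of the inactive X chromosome, at 1.23, although the head of this conceptus had Y-linked RNA.

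The first comparison asked how maternal age relates to expression in the fetal head. Heads from old mothers had less RNA of the lens and of cartilage and more RNA of cell division and of embryonic red cells than heads of young C57 set 2, as tested over fixed lists, while 0 single genes passed the test. Every one of these list calls was lost, with an adjusted p = 0.452 with an estimated correlation. All 18 lens genes had lower means in old heads, with a median log2 difference of -1.69. Among them the crystallins, the structural proteins of the lens, included Crygd (gene 12967) at -3.04 ± 0.92 against -0.59 ± 1.03 and Cryga (12964) at -2.28 ± 1.03 against 0.14 ± 0.99 (SD, n = 4 each). Both had an adjusted p of 0.112 over all genes, and 13 lens genes were lower adjusted over the list alone. Of 17 cartilage and bone genes, 16 had lower means (median -0.43) and 8 were lower adjusted over the list alone. These included Col9a3 (12841), a cartilage collagen chain, at -0.49 ± 0.63 against 0.52 ± 0.25, and Cnmd (16840), which codes for the cartilage protein chondromodulin, at -0.82 ± 0.51 against 0.06 ± 0.26. The lens list had a camera adjusted p of 6.54e-08 and the cartilage list of 4.74e-05. Every other list called in this comparison was lost in the same way (adjusted p 0.452 with an estimated correlation, and 0.619 for the muscle list).

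Cell division genes were called higher in old heads as a group, with a camera adjusted p of 1.83e-09 for mitosis and 6.75e-09 for replication, but 0.452 for both with an estimated correlation. All 22 mitosis genes had higher means (median 0.25), and 17 were higher adjusted over the list alone, among them the spindle motor gene Kif11 (16551) at 0.67 ± 0.30 against 0.22 ± 0.05 and the cyclin gene Ccna2 (12428) at 3.39 ± 0.13 against 3.11 ± 0.14 (SD, n = 4 each). All 20 replication genes had higher means (median 0.23), and 15 were higher adjusted over the list alone, among them Dhfr (13361), needed for thymidylate synthesis, at 0.92 ± 0.20 against 0.55 ± 0.06. Red cell genes were called higher as well, with a camera adjusted p of 2.61e-07 for erythroid genes and 0.00116 for primitive globins, but 0.452 for both with an estimated correlation. Of the erythroid genes 17 of 18 had higher means (median 0.69), and 10 were higher adjusted over the list alone, such as the anion exchanger gene Slc4a1 (20533) at 2.24 ± 0.41 against 1.38 ± 0.36. The 3 primitive globin genes, which serve the first red cells of the embryo, were all higher adjusted over the list alone. Hbb-bh1 (15132) stood at 7.50 ± 0.50 against 6.04 ± 0.90, Hba-x (15126) at 6.86 ± 0.40 against 5.93 ± 0.40 and Hbb-y (15135) at 9.02 ± 0.13 against 8.68 ± 0.06. The primitive globins were the 1 list that fry called (adjusted p 0.0261).

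Neuron genes were called lower in old heads as a group (camera adjusted p 0.00116, and 0.452 with an estimated correlation): 20 of 25 had lower means (median -0.28), and 6 were lower adjusted over the list alone. Examples are the neuronal splicing factor gene Rbfox3 (52897) at 1.41 ± 0.36 against 1.87 ± 0.14 and the axonal adhesion gene L1cam (16728) at 0.35 ± 0.28 against 0.78 ± 0.12 (SD, n = 4 each). Of the 18 macrophage genes 15 had lower means (median -0.22) and 3 were lower adjusted over the list alone, such as the complement gene C1qa (12259) at -1.72 ± 0.23 against -1.30 ± 0.12. Of the 21 interferon-stimulated genes 20 had lower means (median -0.23), and 1, Oasl2 (23962), was lower adjusted over the list alone. The camera adjusted p was 0.00116 for macrophage and 0.000752 for interferon genes, both 0.452 with an estimated correlation. Unfolded protein response genes were higher in 19 of 20 cases (median 0.09, camera adjusted p 0.000825, and 0.452 with an estimated correlation), and 2 of them, Creld2 (76737) and Sdf2l1 (64136), adjusted over the list alone. All 39 ribosomal protein genes had higher means (median 0.11, camera adjusted p 6.56e-10), but 0 were called adjusted over the list alone. The ribosomal median turned to -0.00 under quantile normalization, normexp and the deposited value table, where the adjusted p was 0.633, 0.609 and 0.692, and it was 0.452 with an estimated correlation.

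Of the other lists called in heads, Hox genes of neck and trunk had a median of 1.09, with 17 of 18 means higher and 0 called adjusted over the list alone. The head of young C57 set 2 replicate 3 had a Hox list score of -4.32, and without it the adjusted p rose from 0.00263 to 0.267 (0.452 with an estimated correlation). Muscle genes had a median of -0.40 with 18 of 19 means lower and 0 called adjusted over the list alone. Their adjusted p of 0.0228 rose to 0.802 without old C57 replicate 3 and 0.290 without set 2 replicate 2, was 0.0588 to 0.0638 under the 4 other scalings, and was 0.619 with an estimated correlation. Immediate early genes, which respond within minutes to stimulation, had a median of -0.14, with 14 of 19 means lower and 4 lower adjusted over the list alone, such as Egr1 (13653) at -1.11 ± 0.31 against -0.40 ± 0.37 (SD, n = 4 each). Their adjusted p of 0.02 rose to 0.0977 without old C57 replicate 1, 0.164 without replicate 2, 0.0632 without set 2 replicate 3 and 0.0531 under the stricter filter, and was 0.452 with an estimated correlation. Cholesterol synthesis genes had a median of 0.07 with 19 of 21 means higher and 0 called adjusted over the list alone. Their adjusted p of 0.0163 rose to 0.0610 without old C57 replicate 2, 0.180 without replicate 3 and 0.0775 without set 2 replicate 4, and was 0.452 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.04 with 38 of 42 means higher and 0 called adjusted over the list alone. That median turned negative under quantile normalization, normexp and the deposited value table, and the adjusted p of 0.00343 rose to 0.896, 0.986 and 0.877 there, to 0.110 under median centring and to 0.452 with an estimated correlation.

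Across all 18879 genes tested in heads, limma called 0 at adjusted p under 0.05 for maternal age and 4323 (22.9%) at an unadjusted p under 0.05, of which 1831 were higher and 2492 lower in old heads. Between the groups, 1912 genes (10.1%) had no overlap in any array, where chance gives 2.86%. Between the heads of both young C57 sets, of the same maternal age, 20.5% had an unadjusted p under 0.05. There 21.4% had no overlap, where chance gives 5.71%. The excess over chance is therefore not read as an age effect. The smallest adjusted p, 0.0854, belonged to Prl2a1 (56635) and Ndn (17984). Prl2a1, a placental prolactin family gene, stood at -4.78 ± 0.95 in old heads against -8.50 ± 0.14 (SD, n = 4 each), at least 2.83-fold higher, and every old head lay above every young C57 head, while 1 BTBR head, replicate 4 at -5.41, lay above old C57 replicate 2 at -6.07. Its relative Prl2c5 (107849) stood at -2.90 ± 1.29 against -7.45 ± 1.06, at least 10.3-fold higher (adjusted p 0.112). Ndn, the imprinted gene for necdin, a growth suppressor in neurons, stood at 4.49 ± 0.29 against 5.40 ± 0.10, lower in every old head. Over the alternatives the adjusted p ran from 0.0229 to 0.283 for Prl2a1 and from 0.00772 to 0.259 for Ndn. Leaving out old C57 replicate 1 gave 2116 genes (714 higher, 1402 lower), and leaving out old C57 replicate 2 gave 1. Pooling both young sets gave 1284 (492 higher, 792 lower). Without the head of set 1 replicate 3, which had the most marked spots (693), limma called 0 genes and camera 17 lists.

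**Figure D1:**
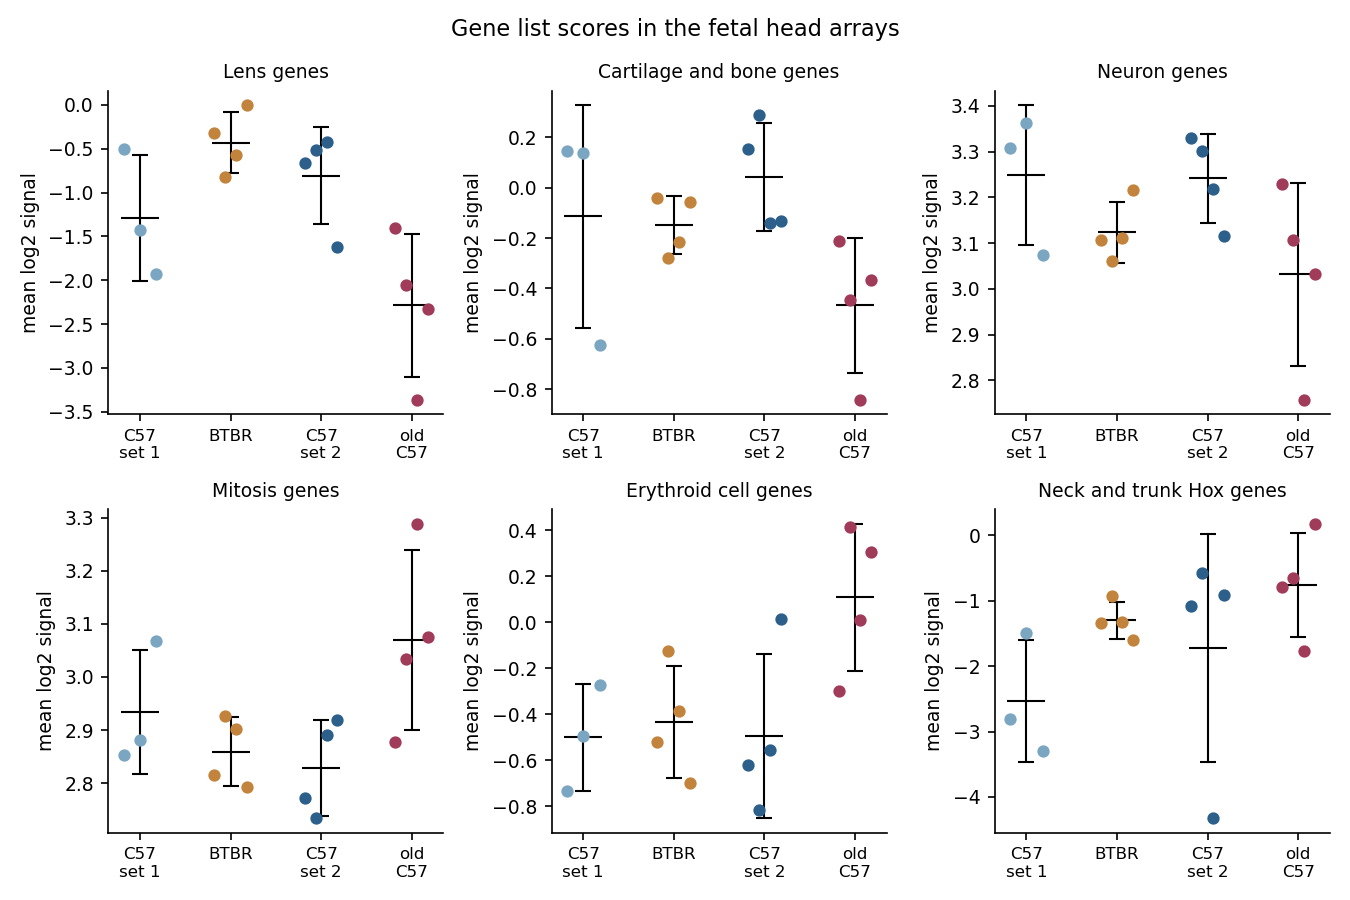
Mean log2 signal over the genes of 6 lists (lens, cartilage, neuron, mitosis, erythroid, Hox) in each of the 15 heads, by group, with bars for the group mean ± SD. Lens scores ran from -3.36 to -1.40 in old C57 heads and from -1.62 to -0.43 in young C57 set 2, and 1 set 2 head had a Hox score of -4.32.

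**Figure D2:**
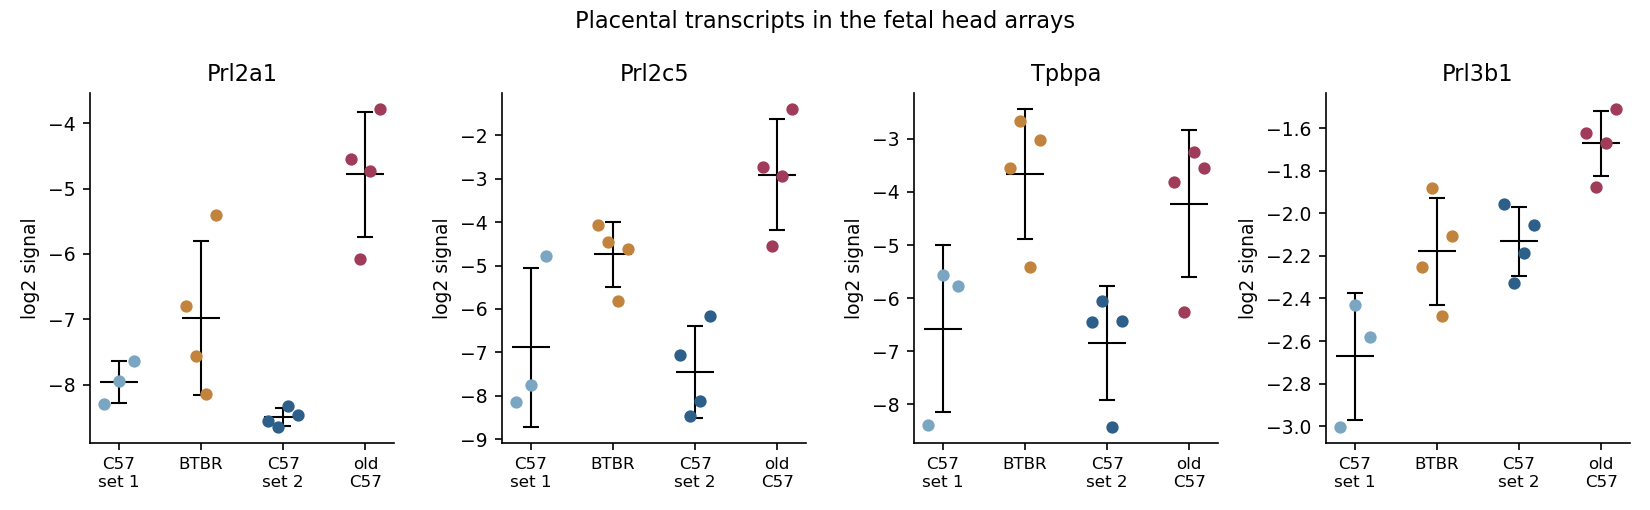
Log2 signal, relative to each array's 75th percentile, of the placental genes Prl2a1, Prl2c5, Tpbpa and Prl3b1 in each of the 15 heads, by group, with bars for the group mean ± SD. Prl2a1 averaged -4.78 in old C57 heads and -8.50 in young C57 set 2.

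The same comparison in placentas asked how maternal age relates to expression there. Placentas labelled old had less RNA of mesenchyme and pericytes, the contractile and matrix-forming cells around vessels, as tested over lists, while limma called 0 single genes. All 16 mesenchyme and pericyte genes had lower means (median -0.30), with 0 called adjusted over the list alone. Among members chosen after their values were seen, Tagln, a smooth muscle actin-binding protein gene, stood at 2.58 ± 0.03 against 3.55 ± 0.74, and Postn, which codes for the matrix protein periostin, at 0.87 ± 0.17 against 1.51 ± 0.33 (SD, n = 4 each). This list had a camera adjusted p of 2.18e-08, kept its call at an adjusted p = 0.0251 with an estimated correlation, and was the 1 list called by fry (0.0208). All 19 decidua genes had lower means (median -0.80), with 1 lower adjusted over the list alone, the collagen gene Col3a1 (12825) at 3.61 ± 0.14 against 4.25 ± 0.12. The camera adjusted p for decidua was 2.71e-06, and 0.521 with an estimated correlation. Old placentas did not move together here: the mean of the decidua genes was 0.600 in replicate 1 and 0.702 in replicate 2 but 3.09 in replicate 3, above every set 2 placenta (1.498 to 2.672). Of 26 nutrient transporter genes 20 had lower means (median -0.15, camera adjusted p 0.00101, and 0.432 with an estimated correlation), and of 20 replication genes 19 had higher means (median 0.15, 0.000395, and 0.627 with an estimated correlation), with 0 members of either called adjusted over the list alone. These 4 lists kept their calls when any 1 array was left out.

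The other 13 lists called in placentas lost their calls without at least 1 array, and each of the 8 arrays ended at least 1 call. All 24 yolk sac endoderm genes had lower means (median -0.68) and 0 were called adjusted over the list alone. Their adjusted p of 0.00201 rose to 0.405 without old C57 replicate 1, 0.525 without replicate 2 and 0.194 without set 2 replicate 4, and was 0.675 with an estimated correlation. The yolk sac marker Afp, which codes for the fetal serum protein alpha-fetoprotein, spanned -0.53 to 7.36 within the old placentas and -0.09 to 7.75 within set 2. Mitosis genes had higher means in 21 of 22 cases (median 0.21, adjusted p 7.11e-05), which was 0.0563 without old C57 replicate 4 and 0.627 with an estimated correlation. The Y-linked list (median -1.62, 4 of 4 means lower, adjusted p 0.0136) rested on the same placenta, with an adjusted p of 0.850 without it and 0.627 with an estimated correlation. Macrophage genes had lower means in 16 of 18 cases (median -0.28). Their adjusted p of 0.00819 rose to 0.338 without old C57 replicate 1, 0.231 without replicate 2, 0.0526 without replicate 4, 0.0676 without set 2 replicate 3 and 0.125 without set 2 replicate 4, and was 0.627 with an estimated correlation. Angiogenesis genes had lower means in 16 of 20 cases (median -0.17) with Angptl4 (57875) lower adjusted over the list alone. Their adjusted p of 0.00223 rose to 0.0573 without old C57 replicate 1 and 0.215 without replicate 2, and was 0.521 with an estimated correlation. Imprinted genes (median -0.09), syncytiotrophoblast genes (median -0.15) and unfolded protein response genes (median -0.07) were called lower, and ribosomal (median 0.09), oxidative phosphorylation (0.08), erythroid (0.31), heat shock (0.10) and cholesterol genes (0.09) higher. Their adjusted p values with an estimated correlation were 0.627, except for imprinted genes (0.644). Adjusted over the list alone, 1 imprinted gene was higher and 1 lower (Kcnq1ot1 and Ndn), the syncytiotrophoblast gene Vgll1 was higher, and 0 members of the other 6 lists or of the mitosis, macrophage and Y-linked lists passed. The cholesterol, heat shock and oxidative phosphorylation calls were also lost under quantile normalization, normexp and the deposited value table. Camera called 11 lists without old C57 replicate 4, the placenta with no Y-linked RNA, and 11 without replicate 2.

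Across the 19240 genes tested in placentas, 1047 (5.4%) had an unadjusted p under 0.05, of which 587 were higher and 460 lower in old placentas, and 555 (2.9%) did not overlap between groups, where chance gives 2.86%. Myocd (214384), a coactivator of smooth muscle genes, had the smallest adjusted p, 0.0889 (range over alternatives 0.0369 to 0.566). It stood at -5.23 ± 0.19 against -4.11 ± 0.17 (SD, n = 4 each), lower in every old placenta, and its adjusted p was 0.0369 without old C57 replicate 3 and 0.441 without replicate 4. Ndn (17984) was at 2.33 ± 0.13 against 2.77 ± 0.10, lower in every old placenta (adjusted p 0.488). Prl2a1 (56635) was at 8.02 ± 0.14 against 7.40 ± 0.21, higher in every old placenta (adjusted p 0.541). Leaving out old C57 replicate 3 gave 24 genes (7 higher, 17 lower), and no other left-out array gave any.

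The maternal make-up of the placenta samples differed between arrays. Xist, which a male conceptus hardly makes, averaged -2.12 ± 0.28 in set 1 and -2.29 ± 0.29 in set 2 (SD, n = 4 each) and was below -3 in 4 placentas, BTBR replicates 1 and 4 and old C57 replicates 1 and 2. In those 4 the mean of the decidua genes was 0.405 to 0.938, against 1.498 to 3.09 in the other 11 placentas with Y-linked RNA, where the highest was old C57 replicate 3. The 2 clusters were read off the values, so no pooled correlation is given. Within the 11, Xist and decidua had r = 0.649 (permutation p 0.0308) and rho = 0.582 (permutation p 0.0656) for this 1 relation, and r = 0.529 without the 2 placentas farthest from the median Xist.

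**Figure D3:**
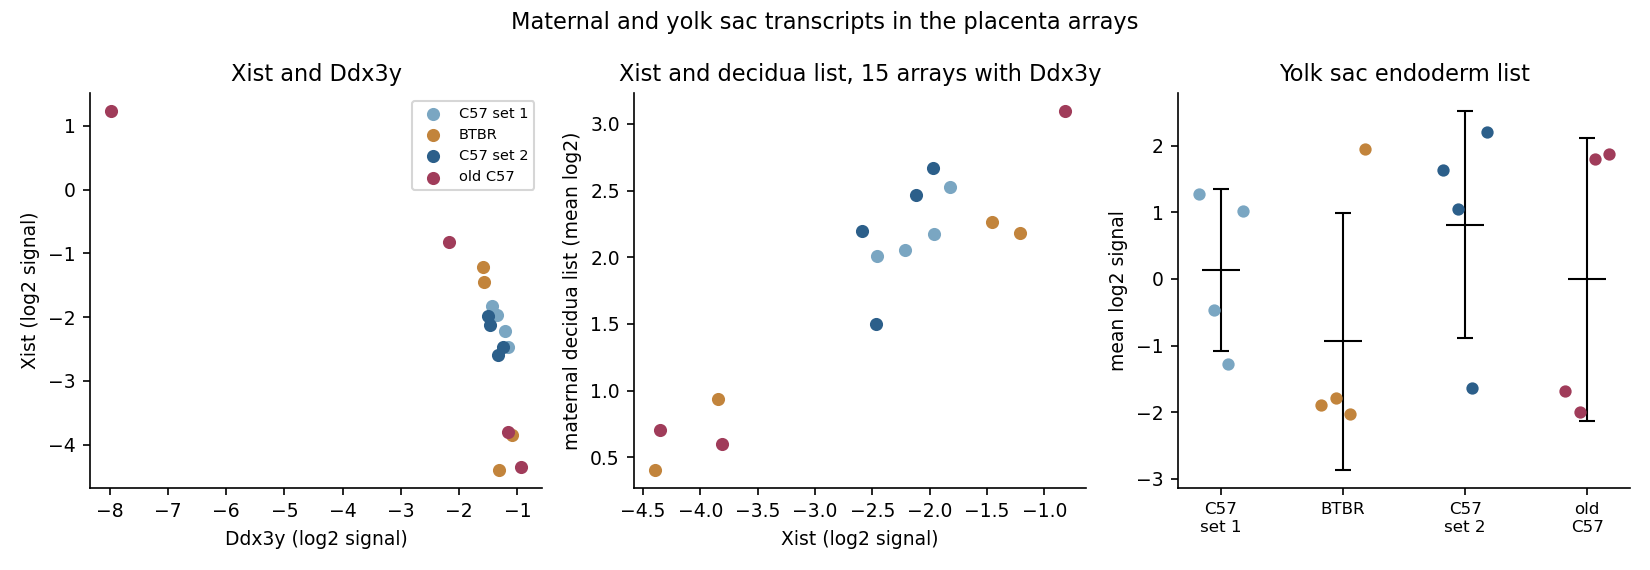
Placenta arrays: Xist against Ddx3y in all 16 (log2 signal), Xist against the mean of the decidua genes in the 15 with Y-linked RNA, and the yolk sac score by group with bars for mean ± SD. The placenta labelled old C57 replicate 4 sits apart with Xist at 1.23 and Ddx3y at -7.98, and 4 placentas with Xist below -3 have decidua means of 0.405 to 0.938.

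The strain comparison asked how young BTBR conceptuses differ from young C57 ones. In heads, the probe of Syt10 (54526), a synaptotagmin of regulated secretion, read far higher in BTBR, at 5.03 ± 0.26 (n = 4) against -4.09 ± 1.05 in C57 set 1 (SD, n = 3, adjusted p 3.43e-08). Ctse (13034), the gene of cathepsin E, was at least 25.3-fold higher. The probe called for Gabra2 (14395), a subunit gene of the GABA-A receptor, read 2.93 ± 0.29 against -1.01 ± 0.31, 15.4-fold higher (adjusted p 8.56e-09), but 3 other Gabra2 probes differed by 1.05, 0.82 and 0.76 on the log2 scale. The probe called for Grn (14824), the progranulin gene, read 9.12 ± 0.14 against 3.64 ± 1.46 (1.45e-05), a difference of 5.49, but 2 other Grn probes differed by -0.07 and 0.10. Lower in BTBR was Pus7l (78895), a pseudouridine synthase relative, at least 31.5-fold. The probe called for Trim12a (76681), a TRIM family gene, was at least 26.4-fold lower, while another differed by -0.88. The probe called for Rbbp9 (26450) read 24.7-fold lower, at -2.81 ± 0.07 against 1.82 ± 0.01 (adjusted p 2.28e-15). In placentas that probe differed by -4.62 but another by 0.69, the other way, and no other Rbbp9 probe could be compared in heads. The histone gene H4c4 (319156) read 17.3-fold lower (another probe by -4.35), and Prim2 (19076), a primase subunit gene, lower by 3.36 on the log2 scale. In every gene named here all 4 BTBR heads lay on 1 side of all 3 C57 heads, which the naming rule required, so it adds no support. Of the 73 named genes called for strain in heads, 34 had another probe to compare, and of the 72 in placentas 24 had. The others, Syt10 among them, rest on 1 probe, so expression and a strain variant under it cannot be told apart.

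Among genes of the lists in BTBR heads, Notch1 (18128), a receptor that keeps neural progenitors undifferentiated, was at 4.05 ± 0.27 against 1.19 ± 0.31 in C57 (SD, n = 4 and 3; adjusted p 1.18e-06), the 1 progenitor gene called out of 18, over all genes and adjusted over the list alone. Of 26 axon guidance genes 1 rose and 3 fell over all genes and adjusted over the list alone. The called probe of the netrin receptor gene Dcc (13176) read 7.88 ± 0.09 against 6.83 ± 0.05 (7.83e-08), but 3 other probes went the other way (-0.46, -0.26 and -0.29). That of the ephrin receptor gene Ephb2 (13844) read 2.91 ± 0.05 against 3.35 ± 0.01 (0.000209), and another differed by 0.31. Among 18 macrophage genes 2 rose and 4 fell (2 and 5 adjusted over the list alone), among them the microglial chemokine receptor gene Cx3cr1 (13051) at -0.76 ± 0.08 against -2.37 ± 0.26 (3.18e-06) and the leukocyte gene Ptprc (19264) at -4.62 ± 0.16 against -3.36 ± 0.16 (3.01e-06). Of 21 cholesterol synthesis genes 1 rose, Hsd17b7 (15490), and 4 fell, including Hmgcs1 (208715), over all genes and adjusted over the list alone. Of 34 autism-associated genes 2 rose and 1 fell over all genes, and 0 adjusted over the list alone. Lens genes were not called in this comparison (15 of 18 means higher in BTBR, median 0.95, camera adjusted p 0.186). The strain marker Nnt (18115), which carries a deletion in C57BL/6J mice, was higher in BTBR heads at 3.01 ± 0.04 against 2.35 ± 0.07 (2.69e-06) and in BTBR placentas at 0.89 ± 0.19 against -0.07 ± 0.16 (0.000346). The other strain marker, Disc1 (244667), was at -1.59 ± 0.15 against -1.96 ± 0.06 in heads (adjusted p 0.0397), a call lost in 12 of 18 alternatives (highest 0.479 with young sets pooled; 0.121 without set 1 replicate 1, 0.0578 without 3, 0.0972 without 4, 0.112 without BTBR replicate 1, 0.0868 without 2 and 0.0582 without 4). In placentas Disc1 was at -2.35 ± 0.13 against -2.55 ± 0.18 (0.415).

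Of 18879 genes tested in heads, 2602 passed for strain, 1250 higher and 1352 lower in BTBR, and 518 of them by at least 2-fold (284 higher, 234 lower). Under median centring the split was 912 higher and 1669 lower. Among the lists, camera called ribosomal protein genes higher in BTBR (37 of 39 means, median 0.08, adjusted p 0.00387, and 0.988 with an estimated correlation), with 3 members called over all genes and 1 adjusted over the list alone. That median was negative under quantile normalization, normexp and the deposited value table (-0.04, -0.04 and -0.05), where the call was lost (0.694 under quantile normalization), and the adjusted p was 0.137 without BTBR replicate 3 and 0.306 under median centring. Without set 1 replicate 1, camera called 3 lists.

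In placentas, Gbp2b (14468), an interferon-induced GTPase gene, was at least 50.9-fold higher in BTBR, at -0.36 ± 0.13 against -8.26 ± 0.08 (SD, n = 4 each; adjusted p 2.13e-09). The probe of Syt10 (54526) read 5.13 ± 0.53 against -2.43 ± 0.72, that of Gabra2 (14395) 1.16 ± 0.56 against -3.72 ± 0.33 and that of Myh4 (17884), a fast muscle myosin gene, 1.22 ± 0.70 against -5.81 ± 0.18. In heads the same Gabra2 probe differed by 3.95 but its other probes by 1.05, 0.82 and 0.76. No gene named in this paragraph had another probe to compare in placentas, so expression and a strain variant under the probe cannot be told apart. Lower in BTBR were the ribonuclease genes Ear2 (13587), at -4.08 ± 1.48 against 3.99 ± 0.74 (adjusted p 0.000487), Ear1 (13586), Ear10 (93725) and Rnase2a (93726). Acoxl (74121), an acyl-CoA oxidase relative, was at least 84.3-fold lower (3.91e-09), and Pus7l at least 37.0-fold lower (8.86e-14). In each of these genes the 4 BTBR placentas did not overlap with the 4 of C57 set 1, which the naming rule required, so it adds no support.

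Trophoblast genes went both ways by strain in placentas. Of 25 spongiotrophoblast and glycogen cell genes 5 rose and 2 fell (6 and 5 adjusted over the list alone): Ceacam9 (26368) was at -2.62 ± 0.24 against 1.95 ± 0.69 (adjusted p 5.43e-08) and Prl6a1 (19111) at 3.24 ± 0.10 against 1.69 ± 0.57 (0.000653; SD, n = 4 each). Of 17 giant cell genes 3 rose and 2 fell (3 and 3 adjusted over the list alone), among them Prl3d1 (18775), the placental lactogen I gene, at 2.94 ± 0.59 against 5.42 ± 0.95 (0.00425). Of 26 syncytiotrophoblast and labyrinth genes 2 rose and 1 fell over all genes and adjusted over the list alone. Gcm1 (14531), a transcription factor needed for labyrinth branching, was at 7.13 ± 0.19 against 5.77 ± 0.28 (0.00123; 2 other probes 1.65 and -0.53), and Synb (239167), a fusion protein of the syncytium, at 0.10 ± 0.25 against 1.59 ± 0.14 (0.000231). Of 26 nutrient transporter genes 3 fell (2 higher and 4 lower adjusted over the list alone), including the amino acid transporter gene Slc7a8 (50934), whose called probe fell by 1.40 on the log2 scale (1.41e-06) and another by 0.31. Their median was 0.10 while their mean was -0.14 and the test pointed down. Macrophage genes were lower in 17 of 18 cases (median -0.46, camera adjusted p 0.0797), with 1 called higher and 3 lower over all genes and adjusted over the list alone, among them the lipid receptor gene Trem2 (83433) at -1.03 ± 1.19 against 3.44 ± 0.28 (0.00126). The decidua markers were lower in 17 of 19 cases (median -0.64) and the yolk sac markers in 21 of 24 (median -0.92), with 0 of either called over all genes or adjusted over the list alone. These medians came from part of the BTBR placentas. Decidua means were 0.938 and 0.405 in replicates 1 and 4 but 2.179 and 2.265 in replicates 2 and 3, against 2.012 to 2.525 in set 1, and the yolk sac score was -2.027 to -1.795 in replicates 1 to 3 but 1.953 in replicate 4.

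Of 19240 genes tested in placentas, 1745 passed for strain, 779 higher and 966 lower in BTBR, and 629 by at least 2-fold (241 higher, 388 lower). The split was 931 higher and 770 lower under median centring and 1510 and 1217 under normexp. Hypoxia and glycolysis genes were called lower in BTBR placentas (26 of 28 means, median -0.18, camera adjusted p 0.00415), a call lost with an adjusted p = 0.956 with an estimated correlation and 0.0547 without BTBR replicate 1. Of them 1 was higher and 3 lower over all genes and adjusted over the list alone. Pdk1 (228026), which restrains pyruvate oxidation, was at 1.38 ± 0.20 against 2.55 ± 0.15 (SD, n = 4 each; adjusted p 3.35e-05), with other probes at -0.65, -0.43 and -0.01 beside -1.18. The called probe of Car9 (230099), a carbonic anhydrase gene, read -1.69 ± 0.03 against -2.20 ± 0.11 (0.00632), and another differed by -0.36, the other way. Replication genes were called higher (19 of 20 means, median 0.16, adjusted p 0.0315), with 0 called over all genes or adjusted over the list alone. That call was lost without set 1 replicate 1 (0.119), set 1 replicate 2 (0.127), BTBR replicate 1 (0.0639) and BTBR replicate 4 (0.0573) and under normexp (0.243), and the adjusted p was 0.956 with an estimated correlation. The adult-type globin gene Hbb-bt (101488143) was at 7.19 ± 0.11 against 8.35 ± 0.19 (3.67e-05).

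The strain differences of head and placenta overlapped. Among 17967 genes tested in both tissues, 326 were called higher in both, from 1210 and 730, and 437 lower in both, from 1283 and 883. If genes were independent, 49.2 and 63.1 would be expected, but they are not, and most conceptuses gave both tissues. Each gene was also read by the same probe in both tissues. A strain variant under a probe could therefore be called in both, so the overlap is not read as shared expression alone. Opposite calls numbered 15 among genes higher in heads and 17 among those lower. The log2 differences had r = 0.392 and rho = 0.198 across genes, which are not independent replicates, and 77.5% of the 2493 genes called in heads had the same sign in placentas.

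**Figure D4:**
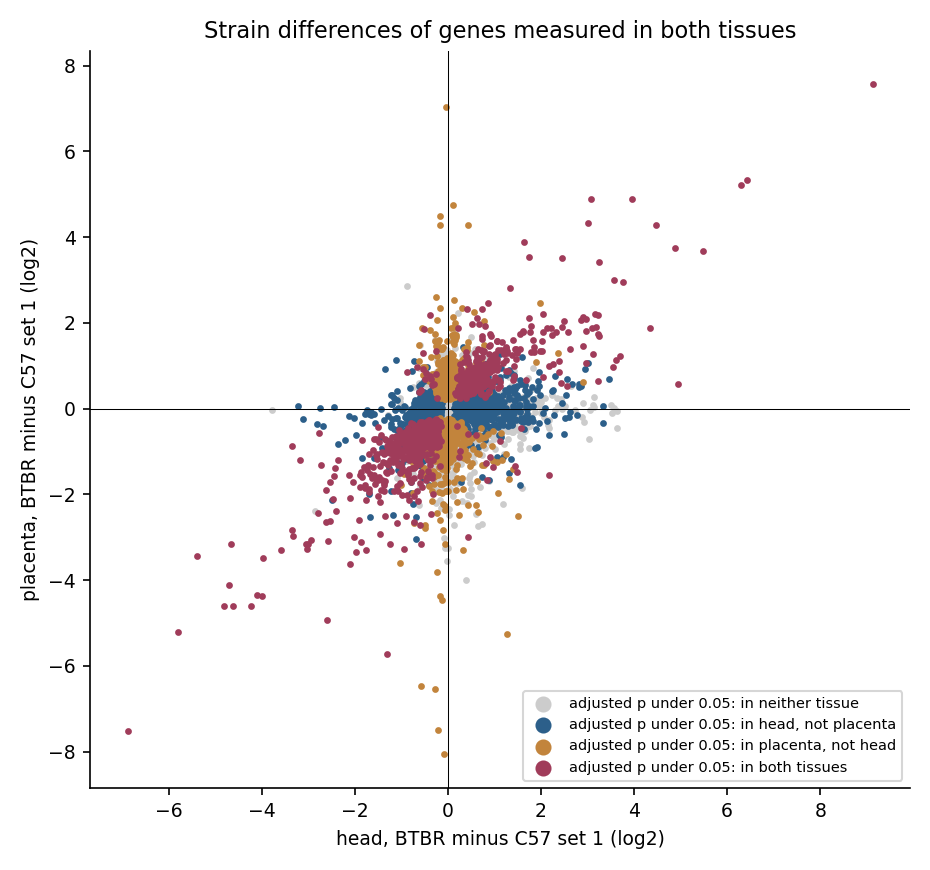
Log2 difference of BTBR minus young C57 set 1 for each of 17967 genes, in heads on the x axis and in placentas on the y axis, with colours for the tissue in which the gene was called. Genes called higher in both tissues numbered 326 and lower in both 437, with r = 0.392 across genes.

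Whether effects differed between the tissues was tested on the head minus placenta difference of each conceptus. For strain, 733 of 20152 genes differed (424 with a positive and 309 with a negative interaction). The interaction was 8.26 for Ear2 (13587, adjusted p 0.0015), 6.96 for Rnase2a (93726, 0.00226) and 6.76 for Ear10 (93725, 0.00933), where a positive value means that BTBR minus C57 was higher in head than in placenta, and -6.99 for Myh4 (17884, 1.04e-05). Ear2 was above background on 2 of 4 BTBR heads, Rnase2a on 3 of 4 BTBR and 2 of 3 C57 heads and Ear10 on 2 of 3 C57 heads. Myh4 was above background on 3 of 4 C57 placentas. These values therefore rest partly on signals near background and are approximate. Acoxl (74121, 6.4e-07) and Ear1 (13586, 0.0224) were called with a positive and Gbp2b (14468, 3.75e-05) and the chemokine gene Cxcl13 (55985, 0.00762) with a negative interaction. In each of these 4 genes at least 1 of the 4 groups had no array above background, so the fitted value is no size and is not given here. The split was 301 positive and 415 negative under quantile normalization, 299 and 606 under median centring, 430 and 622 under normexp and 297 and 442 with the deposited value table. The count was 345 without set 1 replicate 1, 470 without set 1 replicate 3 and 455 without BTBR replicate 1. For age, 1 gene differed, Myocd (214384), with a head minus placenta value of 2.27 ± 0.34 in old conceptuses against 0.51 ± 0.25 (SD, n = 4 each; interaction 1.75 ± 0.21 SE, adjusted p 0.0231), while 1444 genes had an unadjusted p under 0.05. The match of old C57 replicate 4 is in doubt, as its placenta had no Y-linked RNA and its head had. The Myocd call was lost without old C57 replicate 2 (0.0776) or 4 (0.144) and without set 2 replicate 1 (0.0895), 2 (0.126), 3 (0.114) or 4 (0.0808). It was also lost with the replicate number as a block (0.175), and its adjusted p ranged from 0.00353 to 0.175 over the alternatives.

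How far the age difference resembled the strain difference was asked by correlating their log2 values across genes, which are not independent replicates. In heads r was 0.159 and rho 0.235, with r from 0.0582 without young C57 set 2 replicate 3 to 0.220 without set 1 replicate 4. In placentas r was 0.244 and rho 0.118, with r from 0.158 to 0.269 when 1 array was left out. The jackknife SE of r over arrays was 0.154 in heads, about as large as r itself, and 0.133 in placentas. By the reading of the conceptus codes used here, the young C57 controls of both differences share litters. The age and strain differences are therefore not independent, and no shared effect is read from these values.

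Both young C57 sets were compared as a control, where set and slide cannot be told apart. By the reading of the conceptus codes used here, same-numbered conceptuses of the sets are siblings, which the fit ignores. In heads limma called 996 genes, 298 higher and 698 lower in set 1. Thap12 (72981) was at 1.77 ± 0.13 (n = 3) against 1.04 ± 0.17 (n = 4; SD, adjusted p 0.00209), the olfactory receptor gene Olfr397 (258343) at -5.76 ± 0.09 against -4.04 ± 0.13 (0.00185) and Adnp (11538), an autism-associated chromatin gene, at 4.44 ± 0.08 against 4.09 ± 0.06 (0.00375). Autism-associated genes were called higher in set 1 (median 0.07, mean -0.01, camera adjusted p 0.0224, and 0.537 with an estimated correlation), with 2 called higher and 1 lower over all genes, and 4 and 2 adjusted over the list alone. Mitosis genes were called higher (20 of 22 means, median 0.07, 0.00513) and oxidative phosphorylation genes lower (34 of 42 means, median -0.07, 0.0309), both 0.893 with an estimated correlation. Ribosomal genes were called lower (36 of 39 means, median -0.12, adjusted p 7.7e-05), also 0.893 with an estimated correlation, but their median was 0.03, 0.01 and 0.03 under quantile normalization, normexp and the deposited value table. The split was 483 higher and 666 lower under normexp and 434 and 578 with the deposited value table, and the count was 304 without set 1 replicate 1. In placentas limma called 0 genes for set and 1400 at an unadjusted p under 0.05, with a smallest adjusted p of 0.0828 for Olfr1143 (258290). Camera called 3 lists there, ribosomal genes (31 of 39 means higher, median 0.05, adjusted p 0.00271) and definitive globins (5 of 5, median 0.18, 0.0413) higher in set 1 and cholesterol genes lower (17 of 21, median -0.08, 0.0482). Each was 0.995 with an estimated correlation, and 0 members were called adjusted over the list alone. The ribosomal median was -0.00, -0.03, -0.02 and -0.01 under quantile normalization, median centring, normexp and the deposited value table, and the cholesterol median 0.00 under normexp.

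Head and placenta were compared in the 7 young C57 conceptuses of both sets together, on separate slides. By the reading of the conceptus codes used here they came from 4 litters, and siblings were counted as separate replicates. Of 20152 genes 17136 differed, 7433 higher in head and 9703 higher in placenta, and 9364 by at least 2-fold. Among the named genes higher in head, the long noncoding RNA Miat (330166) was at 6.54 ± 0.13 against -5.65 ± 0.40 (SD, n = 7 each, adjusted p 1.33e-10). The transcription factor genes Lhx5 (16873), Tfap2b (21419) and Arx (11878) were at least 350.5-, 359- and 326-fold higher. In placentas the prolactin family gene Prl8a9 (67310) was at least 18586-fold higher and Ceacam11 (66996) at least 14527-fold. Tpbpa (21984), a marker of spongiotrophoblast, was at 8.90 ± 0.10 against -6.73 ± 1.19. Of 25 neuron genes 24 were higher in head (median 6.03) and of 25 spongiotrophoblast genes all 25 in placenta (median -9.39), counts that were equal adjusted over the list alone. All 12 GABAergic neuron genes and all 22 mitosis genes were higher in head, and all 23 interferon-stimulated and all 20 unfolded protein response genes in placenta (medians 5.31, 1.24, -4.51 and -1.99).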

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

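Chosen only after the results were seen were the tests of lens against retina genes, of control genes near background in heads, of placental genes chosen on set 1 heads, of other probes of named genes, of the placenta lists in heads and of fits without a doubted array.

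Heads of old mothers showed 16 shifted gene lists, with less lens, cartilage and neuron RNA and more cell division and red cell RNA, of which 0 were called with an estimated correlation (adjusted p 0.452 to 0.619) and 1 with fry. In the 7 heads of slide 1, the slope of each gene on less lens signal within groups had r = 0.425 with the age difference across 18861 genes, and 1 of 144 reassignments, the real one, reached it (highest other 0.422; 0.00694 is the smallest share possible). Spread in developmental stage between conceptuses is therefore a candidate explanation, though the slopes of Hox (-0.01), ribosomal (0.01), macrophage (-0.00) and interferon genes (0.13 against -0.23) do not follow the age medians. A smaller share of eye tissue cannot be told apart, since the lens score minus the retina score differed by -1.29 (old -1.35 ± 0.69, young -0.07 ± 0.48, SD, n = 4 each; exact permutation p 0.0571). Of 35 splits of the 8 heads, 3 gave 16 lists or more (highest other 16), so chance is not excluded, slide row cannot be told apart from age, and maternal age stays open and untested.

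Prolactin family transcripts stood higher in old heads than in young C57 set 2, Prl2a1 by at least 2.83-fold and Prl2c5 by at least 10.3-fold. Of the 40 genes most abundant in placenta among those at background in all young C57 heads, 87.5% had a higher mean in old heads (median 0.70), but the choice favours this, and 72.6% of 1645 control genes at background in the same heads and in placentas were higher too (median 0.13). With 40 genes chosen on set 1 heads alone the share was 77.5%, under the 80% set beforehand, with a median of 0.70 against at most 0.245 in 10000 draws of 40 controls, so placental RNA in the head samples cannot be told apart from a change in the heads' own expression. The share of placental RNA that each transcript would need was unequal. Among genes already looked at it was 0.0355% for Prl2c5, 0.0226% for Prl2a1, 0.0178% for Prl3b1 and 0.0121% for Tpbpa. For Prl2a1 and Prl2c5 the set 2 heads were at background, so these shares are approximate. Over the first 40 genes the median share was 0.0065% (quartiles 0.0014% and 0.0186%), with 1.83% for Hoxa10. The placenta lists tested in heads were not called (trophoblast giant cell genes, adjusted p 0.263). For the first 40 genes BTBR heads were higher than set 1 heads in 38 and set 1 heads higher than set 2 heads in 30, and maternal age stays open and untested.

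Large strain differences could reflect expression or a strain variant under the probe. For 30 genes lower in BTBR by at least 4-fold there were 42 values of other probes (18 in heads, 24 in placentas, so a probe of a gene called in both counts in both), of which 40.5% moved the same way by at least 50% of the called difference, with a median of -1.08 against -3.08. For 22 genes higher in BTBR there were 32 such values (20 in heads, 12 in placentas), of which 25% did, with a median of 0.23 against 3.06. Expression and probe variants cannot be told apart from these probes, because probes of a gene can also read different transcripts and no probe sequence was compared with the BTBR genome.

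Other splits of the same samples were fitted for each comparison. Only the real split reached the 2602 strain genes in heads (1 of 35 splits, highest other 3) and the 1745 in placentas (1 of 35, highest other 0). The same held for the 733 strain by tissue genes (1 of 35, highest other 1). Chance is therefore unlikely for these strain counts if conceptuses are independent, though 1 of 35 is the smallest share possible. The splits cannot tell strain from slide row, because each group filled its own row. The 17136 tissue genes (1 of 64, highest other 11) exceed chance only if all conceptuses are independent, because by the reading of the codes used here some are siblings. The 996 set genes in heads (1 of 35; highest other 12) exceed chance only if all heads are independent, because same-numbered conceptuses of the sets are siblings by the reading of the codes used here, and 3 such pairs are too few for splits within pairs. Chance is not excluded for the 4323 age genes at unadjusted p in heads (2 of 35; highest other 4604) or the 1047 in placentas (12 of 35; highest other 6283), where the larger splits point to a structure of the placenta samples, though what it follows was not tested. Nor is it for the 17 age lists in placentas (11 of 35; highest other 23), the 1 strain list in heads (34 of 35; highest other 10), the 2 in placentas (32 of 35; highest other 11) or the 1 age by tissue gene (3 of 35; highest other 4). For the 0 age genes in heads (35 of 35; highest other 1), the 0 in placentas (35 of 35; highest other 163) and the 0 set genes in placentas (35 of 35; highest other 3) every split reaches 0, so the splits say nothing.

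Single arrays far from the rest of their group were sought in 446 groups of values, and 20 were found, where chance gives about 1 in 20 groups, or 22.3. Among placentas of old C57, replicate 4 had a Y-linked score of -7.678 (others -1.778 to -0.683) and Kdm5d at -8.178 (others -1.874 to -0.7). Replicate 3 of the same group stood apart for imprinted genes at 2.403 (others 2.89 to 2.966), syncytiotrophoblast genes at 2.01 (2.519 to 2.623) and macrophage genes at 1.365 (-0.326 to -0.042). BTBR placenta replicate 4 had a yolk sac score of 1.953 (others -2.027 to -1.795) and Afp at 7.632 (-0.493 to 0.024), and BTBR placenta replicate 3 a replication score of 1.819 (1.943 to 1.958). In young C57 set 2 placentas, replicate 3 had Afp at -0.092 (others 6.43 to 7.746), and replicate 1 had an angiogenesis score of 0.199 (0.282 to 0.288) and the decidual prolactin gene Prl8a2 at 6.8 (7.755 to 7.891). In set 2 heads, replicate 3 had a Hox score of -4.322 (others -1.085 to -0.569), a cholesterol score of 2.204 (2.094 to 2.109), Ddx3y at -2.471 (-2.29 to -2.273) and Tpbpa at -8.423 (-6.457 to -6.055). Also in set 2 heads, replicate 4 had a hypoxia score of 2.62 (2.497 to 2.511) and replicate 1 had Prl3d1 at -3.257 (-3.534 to -3.497). In old heads, replicate 3 had an autism-associated score of 0.782 (0.841 to 0.845) and replicate 4 had Pgr at -6.873 (-6.008 to -5.899), and BTBR head replicate 1 had a mesenchyme and crest score of 2.076 (2.059 to 2.061).

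Effects that differed between head and placenta by the test of the difference itself were, for age, Myocd (1.75) and, for strain, Ear2 (8.26), Rnase2a (6.96), Ear10 (6.76), Myh4 (-6.99), Cfap70 (-4.75) and Myh8 (-4.43). Part of the heads for Ear2, Rnase2a and Ear10 and of the C57 placentas for Myh4 were not above background, so those values are approximate. For Myh8 the called probe differed by 4.74 between strains in placentas, but another probe by -0.47, so its value holds for the called probe only. Ear1, Acoxl, Gbp2b and Cxcl13 were also called, but 2 groups for Gbp2b and 1 each for the others had no array above background, so their fitted values (7.12, 7.09, -5.84 and -4.58) are differences against background and no sizes. The Ear1 call was lost without set 1 replicate 1 (adjusted p 0.0917), set 1 replicate 3 (0.0781), BTBR replicate 1 (0.0662) or BTBR replicate 4 (0.0598), with a range of 0.0112 to 0.0917 over its alternatives. The Myocd call was lost without old C57 replicate 2 (0.0776) or 4 (0.144), whose head and placenta match is in doubt, and without any 1 array of set 2. It was also lost with the replicate number as a block (adjusted p 0.175).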

How the results depend on the processing

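Chosen only after the results were seen were the tests without 1 doubted head or placenta. Of 7312 values of named genes under alternatives, 6585 kept their side of the threshold, 399 lost their call, 326 gained one and 2 reversed. A value counted as reversed where its sign changed and either fit called it. A change of sign between values that neither fit called counted as kept. Of 644 list values, 498 kept their call and 146 lost it. Signal over background limits genes near the floor, given as bounds, and the placenta list counts rest on few arrays. Where a value moved, the cause was not tested, except that all probes, the fold minimum and left-out arrays change the number of features or samples.

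Genes called for age in heads numbered 2 under normexp, 1 with the deposited value table, 2 with trend and robust options, 0 to 2116 with 1 array left out, 1284 with young sets pooled and 1577 with litter code as a block as well. In placentas they numbered 0 to 24 with 1 array left out and 1 with the replicate block. For strain in heads they numbered 1107 with the fold minimum, and in placentas 2727 under normexp and 1658 without the placenta labelled old C57 replicate 4. For set in heads they numbered 3083 over all probes, 304 to 963 with 1 array left out, 389 with only the compared groups, 523 with the replicate block and 243 with the fold minimum, and in placentas 325, 613 and 0 to 1 under normexp, over all probes and with 1 array left out. For age by tissue they numbered 3 under normexp and with the deposited value table, 0 with the replicate block and 0 to 4 with 1 array left out. For strain by tissue they numbered 345 to 637 with 1 array left out. Over all probes the counts are of probes, not genes. They were 5298 for strain in heads, 3694 for strain in placentas, 3083 for set in heads and 613 for set in placentas. For age by tissue 0 probes were called, for strain by tissue 1302 and for tissue 37868.

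Lists called for age in heads numbered 0 with an estimated correlation and 1 with fry, and in placentas 1 with either and 11 to 18 with 1 array left out. For strain in heads they numbered 0 under quantile normalization, normexp, the deposited value table, an estimated correlation and fry, 2 under median centring and 0 to 3 with 1 array left out, and in placentas 1 under normexp, 0 with an estimated correlation and 0 to 6 with 1 array left out. In strain placentas Hspb1 reversed from -0.32 to 0.0837 and Hba-a1 from -0.34 to 0.00948 under normexp (adjusted p over alternatives 0.0136 to 0.59 and 0.0164 to 0.936). By the reading of the conceptus codes used here, a replicate number marks 1 litter in both young C57 sets, but the labels do not say so. Deviations of same-numbered arrays had r of -0.20 to 0.30 for set in heads, -0.15 to 0.45 for set in placentas (3 of 4 pairs over 0.1), -0.01 to 0.51 for age in placentas (3 of 4) and 0.01 to 0.08 for age in heads, and in no comparison did every array correlate best with its own number, so the replicate block was no main choice.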

Other observations

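Chosen only after the results were seen was the test of overlap at an unadjusted p.

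Choroid plexus genes, whose epithelium makes cerebrospinal fluid, were not called as a list for age in heads (camera adjusted p 0.615), but 4 of 13 were lower adjusted over the list alone. Ttr (22139), the thyroid hormone carrier of that epithelium, was at 2.58 ± 0.47 in old heads against 3.42 ± 0.28 (SD, n = 4 each; adjusted p 0.112 over all genes). Calml4 (75600) was at -2.91 ± 0.63 against -1.94 ± 0.19 and Kcne2 (246133) lower by a log2 difference of -0.70. Of 15 retina and pigment genes 2 were lower adjusted over the list alone, Atoh7 (53404), needed for retinal ganglion cells, at -1.64 ± 0.97 against -0.27 ± 0.41 and Rlbp1 (19771) at -2.74 ± 0.58 against -1.59 ± 0.53. Of 34 autism-associated genes 3 were lower adjusted over the list alone, Nlgn3 (245537), Cacna1c (12288) and Pten (19211), with differences of -0.33, -0.31 and -0.22 (list adjusted p 0.114). The glycolytic gene Aldoc (11676) was at 0.59 ± 0.72 against 2.07 ± 0.56 (adjusted p 0.112).

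Single members of the stress, metabolic and interferon lists differed by strain, and those given here do not stand for their lists. Sod2 (20656), the mitochondrial superoxide dismutase gene, was higher in BTBR heads at 1.75 ± 0.07 (n = 4) against 1.31 ± 0.12 (n = 3; SD, adjusted p 0.00106) and in BTBR placentas at 1.84 ± 0.05 against 0.95 ± 0.07 (2.16e-06; n = 4 each). Cox7a2 (12866), a cytochrome oxidase subunit gene, was lower in both, by -0.46 and -0.44 (4.77e-05 and 0.00174). Uqcrb, of the same list, was higher in BTBR heads by 0.20, a call lost in 9 of 18 alternatives. Sec61b (66212), part of the channel into the endoplasmic reticulum, was at 6.05 ± 0.09 against 5.31 ± 0.06 in heads (3.23e-06), where another probe differed by 0.16. The called probe of Stat1 (20846), an interferon signal transducer gene, read -1.53 ± 0.08 against -2.24 ± 0.08 in heads (8.96e-05), and another differed by -0.25, the other way.

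At an unadjusted p under 0.05, 96 genes were higher with age in both tissues and 116 lower. If genes were independent, 54.2 and 49.3 would be expected, but genes are not independent and both tissues came from the same conceptuses. Chance was not excluded for either set of genes (2 of 35 splits as large in heads and 12 of 35 in placentas). No shared age effect is therefore read from the overlap. Opposite directions numbered 15 among genes higher in heads and 46 among those lower, and the age differences had r = 0.189 and rho = 0.225 across genes.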
